A study of Mus musculus with 18 samples.

How the data were processed

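Liver RNA of 18 C57BL/6 mice was sequenced, 3 in each of 6 groups: normal diet, high-fat diet, and high-fat diet with schisandrin C at 20 mg/kg, schisandrin C at 100 mg/kg, simvastatin at 100 mg/kg, or schisandrin C together with simvastatin. The label of the last group gives 100 mg/kg once, so the schisandrin C dose in the combination is not stated without doubt. Per the labels, RNA was extracted with TRIzol and made into stranded mRNA libraries. The labels give each library as a separate sample, and the p values below measure the spread between these samples.

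The deposited table holds FPKM (fragments per kilobase of transcript, scaled for library size) computed by the authors. It has 24353 genes by symbol and locus and a column per sample. The processing notes name STAR 2.5.0, Cufflinks without a version and Cuffdiff 2.2.1, and the builds mm10 and hg19, without giving the role of each. Of the symbols, 23314 were found in GENCODE M21, and 98.84% of the loci on file for these overlapped the GENCODE gene on mm10. Of the symbols, 5571 shared a locus with another symbol. Reads of near-identical genes (the Mup, Serpina1, Cyp3a, Cyp2b, Cyp2c, Gstm, Ugt1a, Cyp4a, Acot and Selenbp families) cannot be assigned without doubt in such values. FPKM values do not give the read depth, so depth is unknown and no counting interval or floor is given. The column names of normal diet replicate 11 and of high-fat diet replicates 9 and 11 carry suffixes that no label explains. No pair of libraries held identical values, and no value column lacked a sample. Values of 1 table line withheld from the files were not analysed here.

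Values were taken as log2(FPKM + 1). The 10923 genes with a mean of at least 1 FPKM over the 18 libraries were tested, and 4743 genes were at 0 in every library. R 4.3.3 and limma 3.58.1 were used. All 6 groups entered a single limma fit (lmFit, contrasts.fit and eBayes with an intensity trend, 12 residual degrees of freedom), with two-sided moderated tests, Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05 on the adjusted p. Fold changes are log2 ratios of FPKM + 1 and understate ratios of low values. Errors of FPKM are SD over 3 libraries, and errors of log2 fold changes are SE. The comparisons were high-fat against normal diet, each treatment against the high-fat diet, and 4 pairs of treatments. A limma F-test over all groups and a contrast for departure from additivity of the combination were added.

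The comparisons, filters, tests, alternatives and 31 gene lists were fixed before the data were examined. Lists came from textbook knowledge of liver biology and of the drugs. The 23 lists with at least 5 measured members were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and limma's fry stood beside it, and 8 lists had too few members. Of the 207 list tests in the 9 comparisons, 64 passed with camera and 32 with fry, which tests whether a list's genes move one way and does not compare them with other genes. None of the 207 passed with an estimated correlation. Members called were counted over all genes tested and adjusted over the list alone.

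Genes were named by a fixed rule: the 3 genes of the series title, the 10 highest and 10 lowest log2 fold changes among called genes whose libraries do not overlap between the groups (predicted and unnamed genes left out), up to 4 called members of each list with the smallest adjusted p, and, where fewer than 5 genes passed, the 6 genes with the smallest p. Per-library values of Arntl, Cxcl13, Ddx3y and Xist and a clock score were added after the data were seen. The score is the mean deviation of Arntl, Clock, Npas2 and Nfil3 minus that of 8 genes in the opposite phase.

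Recovery was tested on simulated data with the spread of these libraries. Of 100 genes changed 2-fold in each comparison, 80 to 95 were called, and of 100 changed 4-fold, 93 to 98, with 5 to 11 false calls. The noise was drawn independently for each gene and library, with no correlated genes and no outlying library. These rates therefore hold for such data and may not hold for the real libraries. Alternatives were another pseudocount (0.1), no filter and a filter at 5 FPKM, median-of-ratios and quantile scaling, robust eBayes, array weights, the number in the sample title as a block, fits of the 2 groups compared alone, and leaving out each library in turn. After the data were seen, 3 more were added: removal of each library's trend with GC content (loess, span 0.5), leaving out 2 libraries together, and the clock score as a covariate.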

Results

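The data are FPKM values of 18 mouse liver libraries, 3 per group, from animals on a normal or a high-fat diet and from high-fat-fed animals given schisandrin C (a lignan of Schisandra fruit) at 20 or 100 mg/kg, simvastatin (a cholesterol-lowering statin) or both. Read depth is unknown. The FPKM sums ranged from 649886 to 966964, and small RNA genes took 26.2% to 48.4% of each sum. Genes above 0 numbered 14307 to 15343 in 17 libraries and 17084 in high-fat diet replicate 1. Pearson's r across genes between any 2 libraries was 0.893 to 0.963. Over all 6 groups, 5071 of 10923 genes differed (limma F-test, adjusted p under 0.05). Called genes mostly separated the groups: 780 of 796 called between the diets had no overlap between the 3 libraries of each group, and 1725 of 1755, 845 of 880, 73 of 73 and 1285 of 1304 with the 4 treatments in the order above. Over all genes 16.5% to 35.5% did not overlap in these 5 comparisons, where chance gives 10%.

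Clock genes set 2 libraries apart from their groups, and GC content set all 3 libraries of a group apart from the others. Arntl, the core activator of the circadian clock, stood at 7.44 to 10.9 FPKM on the normal diet, 7.46 in high-fat diet replicate 1 and 5.77 in simvastatin replicate 1, and at 0.252 to 1.27 in the other 13 libraries. The clock score was 2.29 to 2.98 on the normal diet, 2.23 and 1.30 in those 2 libraries, and -1.18 to -0.37 in the other 13. High-fat diet replicate 1 and simvastatin replicate 1 are called the 2 clock-shifted libraries. High-fat diet replicate 1 also held 40.5 FPKM of the chemokine Cxcl13 and 116 FPKM of the Kupffer cell gene Clec4f, against 0.401 and 42.4 in replicate 9 and 0.506 and 51.3 in replicate 11. In the schisandrin C 20 mg/kg libraries the deviation from the gene means correlated with GC content across genes at rho -0.57, -0.42 and -0.36, and in the other 15 at -0.23 to 0.42. Genes are not independent replicates.

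**Figure D1:**
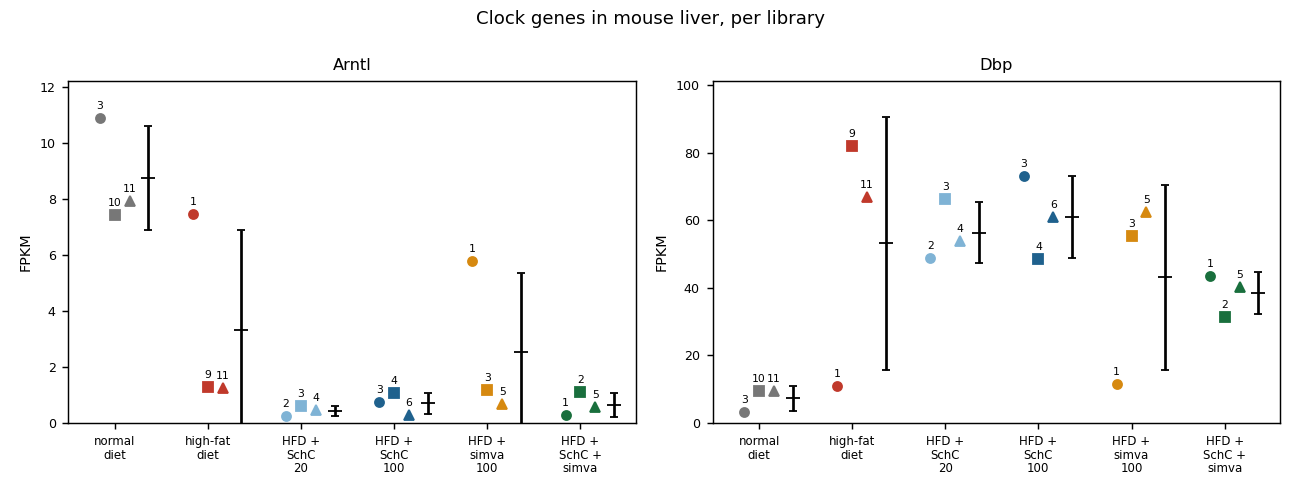
FPKM of the clock genes Arntl and Dbp in each library (points, numbered by replicate, SchC for schisandrin C, simva for simvastatin) with the group mean and SD (bars, n = 3). Arntl stands at 7.46 FPKM in high-fat diet replicate 1 and 5.77 in simvastatin replicate 1, and at 1.27 or less in the other high-fat-fed libraries.

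**Figure D2:**
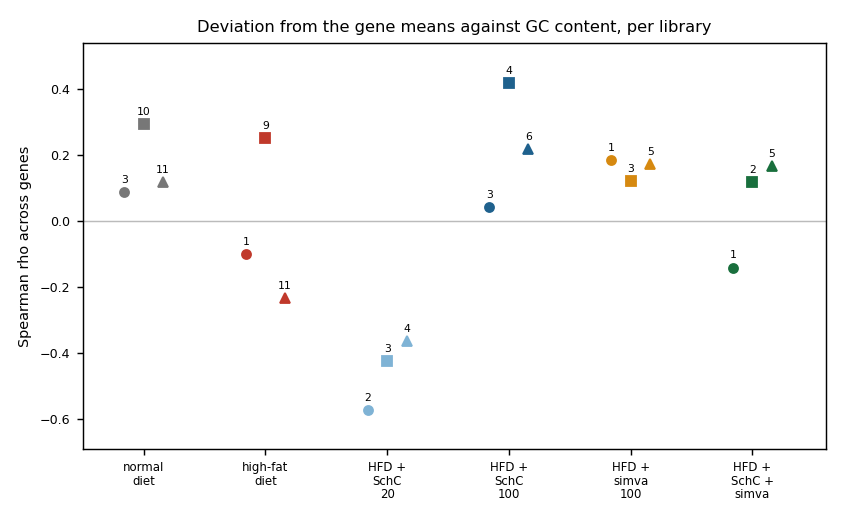
Spearman's rho across genes between each library's deviation from the gene means and transcript GC content, per library (points, numbered by replicate). The 3 libraries of schisandrin C at 20 mg/kg stand at -0.57 to -0.36, below the other 15 at -0.23 to 0.42.

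The series title names Cd36, Cyp7a1 and Cyp7b1. Cyp7a1, the rate-limiting enzyme of bile acid synthesis (chromosome 4, 6265612 to 6275633 on mm10), rose from 3.52 ± 1.85 FPKM (SD, n = 3) on the normal diet to 28.9 ± 13.2 on the high-fat diet. It rose further with each treatment, to 157 ± 61.4 with schisandrin C at 20 mg/kg, 72.1 ± 17.4 at 100 mg/kg, 101 ± 31.1 with simvastatin and 107 ± 19.96 with the combination. Cyp7b1, an oxysterol hydroxylase of the alternative bile acid pathway (chromosome 3, 18071950 to 18243338), rose from 53.8 ± 19.4 to 286 ± 135 FPKM with the diet and fell to 68.5 ± 38.7 with schisandrin C at 100 mg/kg and 48.2 ± 23.6 with the combination. Cd36, a fatty acid transporter (chromosome 5, 17781690 to 17888801), rose from 9.98 ± 0.805 FPKM on the high-fat diet to 38.1 ± 19.7 with schisandrin C at 100 mg/kg and 40.0 ± 13.2 with the combination.

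For Cyp7a1 the log2 fold changes were 2.68 (SE 0.39, adjusted p = 0.00181) for the diet, 2.44 (adjusted p = 0.00248) for 20 mg/kg, 1.39 (adjusted p = 0.0419) for 100 mg/kg, 1.84 (adjusted p = 0.0474) for simvastatin and 1.96 (adjusted p = 0.00501) for the combination. For Cyp7b1 they were 2.31 (SE 0.50, adjusted p = 0.0141) for the diet, -2.05 (adjusted p = 0.0205) for 100 mg/kg and -2.51 (adjusted p = 0.00492) for the combination. Those that did not pass were -0.63 for 20 mg/kg (adjusted p = 0.402) and -1.54 for simvastatin (adjusted p = 0.184). For Cd36 they were 1.67 (SE 0.47, adjusted p = 0.0405) for 100 mg/kg and 1.84 (adjusted p = 0.0192) for the combination. The diet (0.68, adjusted p = 0.401), 20 mg/kg (1.42, adjusted p = 0.051) and simvastatin (1.55, adjusted p = 0.153) did not pass for Cd36. Of the 3 title genes 2 rose with the diet, 1 with 20 mg/kg and 1 with simvastatin, and 2 rose and 1 fell with 100 mg/kg and with the combination. With the p adjusted over the list alone 2 rose with the diet and with 20 mg/kg, and 2 rose and 1 fell with each of the other treatments. These genes come from the title of the series itself, so these counts are not independent evidence. In every comparison that passed here, the 3 libraries of a group lay on the same side of the 3 of the other.

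Of the 18 fits that left out 1 library, the 100 mg/kg calls passed in 8 for Cd36, 10 for Cyp7a1 and 14 for Cyp7b1, and the simvastatin call of Cyp7a1 passed in 4. The highest adjusted p of these were 0.163 (without replicate 6 of that group), 0.174 (without high-fat diet replicate 1), 0.11 (without replicate 4 of that group) and 0.19 (without simvastatin replicate 1). The diet call of Cyp7b1 passed in 16 (0.0688 without normal diet replicate 10) and the combination call of Cd36 in 15 (0.0764 without combination replicate 1). The diet, 20 mg/kg and combination calls of Cyp7a1 and the combination call of Cyp7b1 passed in all 18.

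**Figure D3:**
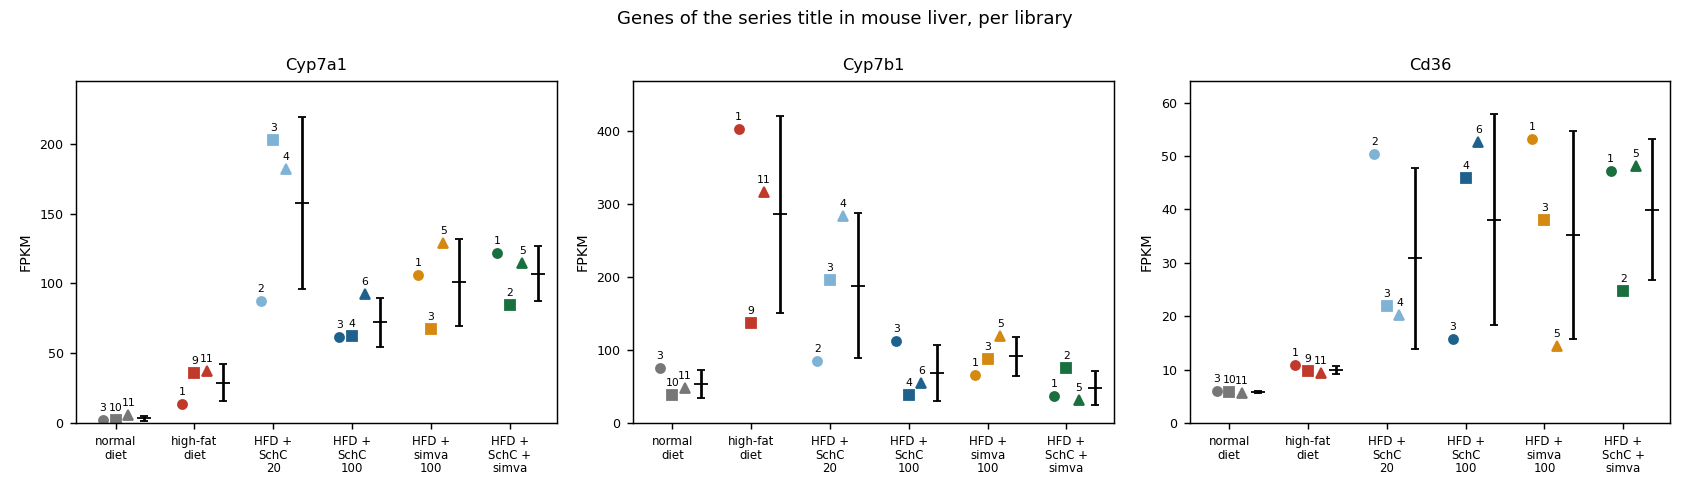
FPKM of Cyp7a1, Cyp7b1 and Cd36 in each library (points, numbered by replicate, SchC for schisandrin C, simva for simvastatin) with the group mean and SD (bars, n = 3). Cyp7a1 averages 3.52 FPKM on the normal diet, 28.9 on the high-fat diet and 72.1 to 157 in the treated groups.

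Between the diets, Scd1, Igfbp1 and Fgf21 were lower and Mup9 higher on the high-fat diet. Scd1, the desaturase of oleate synthesis, fell from 4788 ± 869 to 533 ± 637 FPKM (SD, n = 3, log2 fold change -3.86, SE 0.71). Igfbp1, an insulin-repressed binding protein, fell from 140 ± 52.6 to 8.62 ± 12.01 FPKM (log2 fold change -4.66, SE 0.81), and Fgf21, a fasting hormone, from 11.7 ± 2.63 to 1.24 ± 0.542. Mup9 rose from 0.486 ± 0.374 to 41.2 ± 16.0 FPKM (log2 fold change 4.80, SE 0.64). In limma, 390 genes were higher and 406 lower.

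Of 20 measured genes of fatty acid synthesis, 6 fell, none rose and 14 did not pass (8 fell adjusted over the list alone). Elovl5 (-2.30), Acacb (-2.51) and the NADPH source Me1 (-2.82) fell with Scd1 (camera adjusted p = 1.36e-05; adjusted p = 0.45 with an estimated correlation). Of 16 glucose metabolism genes, 4 fell: Igfbp1, the insulin receptor substrate Irs2 (-1.97), the gluconeogenic Pck1 (-1.38) and the aminotransferase Tat (-1.37). None rose, and 5 fell adjusted over the list alone (camera adjusted p = 0.000329; adjusted p = 0.45 with an estimated correlation). Of 19 lipid uptake and droplet genes 4 fell, among them Plin5 (-1.68) and Plin4 (-2.20), and adjusted over the list alone 1 rose and 5 fell (camera adjusted p = 0.231). Of 29 PPARA targets 5 fell, among them Fgf21, Ppargc1a (-0.90) and Crat (-1.07), with 6 adjusted over the list alone (camera adjusted p = 0.0251; adjusted p = 0.774 with an estimated correlation). The 3 normal diet libraries also differed from high-fat diet replicates 9 and 11 in clock score, with which Dbp (2.41) and Hlf (0.64) rose and Nfil3 (-1.77) fell among 17 clock genes (7 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.339).

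Of 15 measured pericentral hepatocyte genes 8 rose, none fell and 7 did not pass (12 rose adjusted over the list alone). Cyp2e1, an ethanol-metabolising enzyme, rose from 2260 ± 465 to 5048 ± 983 FPKM, with Cyp1a2 (1.17), Cyp2a5 (2.27) and Lect2 (1.12). The camera adjusted p was 5.16e-09, and the adjusted p = 0.136 with an estimated correlation. Of 14 periportal genes 1 rose (Aldh1b1, 1.11) and 3 fell (Sdsl, -1.34, Pck1 and Sds, -1.22), with 1 and 4 adjusted over the list alone (camera adjusted p = 0.0474; adjusted p = 0.533 with an estimated correlation). Of 14 male-biased liver genes 5 rose and none fell (7 and 1 adjusted over the list alone), among them Selenbp2 (3.8), Susd4 (1.93), Cyp7b1 and Nudt7 (1.43), with camera adjusted p = 0.000513 and adjusted p = 0.533 with an estimated correlation. Mup1 (4.87), Mup12 (4.35), Mup7 (4.32), Mup14 (3.69), Mup8 (2.35) and Nrep (2.65) were the other genes with the largest rises, and Cdkn1a (-3.26), Zbtb16 (-3.07) and the tetraspanin Cd9 (-2.44) the other largest falls. Of 13 bile acid synthesis genes 3 rose and 1 fell (6 and 1 adjusted over the list alone), Akr1c14 (0.85) rising and Cyp39a1 (-1.81) falling beside the title genes (camera adjusted p = 0.011; adjusted p = 0.45 with an estimated correlation).

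Without the 2 clock-shifted libraries 794 genes passed, of which 522 were shared, and fatty acid synthesis had 5 falls, glucose metabolism had 4 falls and 1 rise, pericentral genes 6 rises and clock genes 9 rises and 4 falls. That fit cannot separate diet from clock. High-fat diet replicates 9 and 11 (clock scores -1.08 and -0.76) and the normal diet libraries (2.29 to 2.98) then differ in both. With the clock score as a covariate 397 passed, 247 of them shared. Within these 2 groups only high-fat diet replicate 1 separates diet from clock score, so the diet calls above may partly follow the clock. Without normal diet replicate 3, 495 passed, without normal diet replicate 10, 285, and without high-fat diet replicate 11, 231. Of 58 genes named here and called, 32 passed in all 18 fits that left out 1 library. For others, brackets give the highest adjusted p in these fits and the number of the 18 that passed. The highest came without normal diet replicate 10 for Plin4 (0.122, 14), Mup7 (0.124, 14), Mup14 (0.0734, 16), Sds (0.194, 8), Nfil3 (0.129, 14), Nudt7 (0.102, 16), Akr1c14 (0.142, 16) and Cyp39a1 (0.0716, 14), and without high-fat diet replicate 11 for Dbp (0.151, 13), Hlf (0.0983, 14) and Zbtb16 (0.103, 15).

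Schisandrin C at 20 mg/kg was compared with the high-fat diet alone. Cyp3a11, the main drug-metabolising cytochrome of mouse liver, rose from 353 ± 29.0 to 20810 ± 11210 FPKM (SD, n = 3, log2 fold change 5.76, SE 0.35). Cyp2b10, a marker of the receptor CAR, rose from 0.424 ± 0.650 to 63.7 ± 82.6 FPKM (log2 fold change 4.68, SE 0.81), and the carboxylesterase Ces2a from 90.3 ± 20.6 to 779 ± 370. In limma, 1158 genes were higher and 597 lower. With quantile scaling these were 727 and 626.

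Of 21 measured xenobiotic metabolism genes, 13 rose, none fell and 8 did not pass (15 rose adjusted over the list alone). They include Cyp2c55 (5.24), Cyp2c29 (2.57) and Cyp3a25 (2.11), and the adjusted p was 3.92e-11 with camera and 0.245 with an estimated correlation. Of 19 glutathione and NRF2 targets 9 rose and none fell, and adjusted over the list alone 13 rose and 2 fell, Gstm3 (4.04) and Gstm4 (1.29) among the first (camera adjusted p = 0.00275; adjusted p = 0.992 with an estimated correlation). Replicate 2 held more of these products than replicates 3 and 4: Cyp2b10 at 159, 22.6 and 9.71 FPKM and Gstm3 at 707, 24.0 and 23.5. Of 12 bile acid transport genes 3 rose, the uptake carrier Slco1a4 (4.05), the export pump Abcc3 (1.75) and Klb (0.68), with 4 up and 1 down adjusted over the list alone (camera adjusted p = 0.0157; adjusted p = 0.245 with an estimated correlation). Of 13 bile acid synthesis genes 3 rose, Cyp7a1, Akr1d1 (1.55) and Akr1c14 (1.14), and Cyp39a1 (-1.60) fell, with the same counts adjusted over the list alone (camera adjusted p = 0.312). Of 25 cholesterol synthesis and uptake genes 2 rose, none adjusted over the list alone, with a median log2 fold change of 0.61 (camera adjusted p = 0.00497; adjusted p = 0.992 with an estimated correlation). Of 13 cholesterol efflux genes 2 fell, Apoe (-0.80) and Pltp (-0.86), and 2 adjusted over the list alone (camera adjusted p = 0.0838). Cyp3a59 (5.15), Snhg9 (2.88) and Cyp26a1 (2.59) were other large rises. Foxq1 (-2.19), Ppp1r14a (-1.80), Derl3 (-1.63), Ces4a (-1.42), Osgin1 (-1.41), Chka (-1.36), Avpr1a (-1.36), H2-Q9 (-1.34) and Rtn4rl1 (-1.23) were the other large falls.

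Leaving out the 2 clock-shifted libraries, 828 genes passed, 736 of them shared, with 12 xenobiotic and 4 NRF2 genes higher; with the GC trend removed 1047 passed, 813 of them shared, with 13 and 6. Leaving out high-fat diet replicate 1 gave 1000, high-fat diet replicate 9 gave 1150, and replicates 2 and 4 of the treated group gave 610 and 1061. Of 46 named genes called, 21 passed in all 18 fits that left out 1 library. For others, brackets give the highest adjusted p in these fits and the number of the 18 that passed. The highest came without high-fat diet replicate 1 for Chka (0.121, 14), Osgin1 (0.0616, 15), Pltp (0.191, 4) and Snhg9 (0.119, 14), and without high-fat diet replicate 9 for Cyp39a1 (0.0839, 15). It came without treated replicate 2 for Apoe (0.0831, 16), Avpr1a (0.102, 16), Ces4a (0.0682, 15) and Derl3 (0.0822, 16), without replicate 3 for Cyp26a1 (0.147, 13) and without replicate 4 for Foxq1 (0.101, 14).

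Schisandrin C at 100 mg/kg was compared with the high-fat diet alone. Gstm3, a glutathione transferase, rose from 3.70 ± 1.16 to 1454 ± 655 FPKM (SD, n = 3, log2 fold change 8.18, SE 0.95). Cyp3a11 rose to 23260 ± 3602 FPKM (log2 fold change 6.03, SE 0.35) and Cyp2b10 to 227 ± 79.6 (7.35, SE 0.81). In limma, 558 genes were higher and 322 lower, and with quantile scaling 487 and 384.

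Of 21 xenobiotic metabolism genes 15 rose, none fell and 17 rose adjusted over the list alone, with Cyp2c55 (7.91), Ces2a (4.29) and Cyp2c29 (3.77); the camera adjusted p was 2.15e-19 and the adjusted p = 0.156 with an estimated correlation. Of 19 NRF2 targets 11 rose, none fell and 13 rose adjusted over the list alone, with Gstm1 (2.84) and Gstm2 (3.32) (camera adjusted p = 1.5e-08; adjusted p = 0.414 with an estimated correlation). Gsta1 was listed at 0 in all 3 high-fat diet libraries and at 17.1, 63.2 and 59.0 FPKM here. Of 25 cholesterol synthesis and uptake genes 7 rose, none fell and 19 rose adjusted over the list alone, with Dhcr7 (1.23), Acat2 (1.15) and Fdps (1.38) among them (camera adjusted p = 4.49e-09; adjusted p = 0.636 with an estimated correlation). Of 20 fatty acid synthesis genes 5 rose, none fell and 11 rose adjusted over the list alone, with Acss2 (1.29), Elovl6 (2.26), Acacb (2.10) and Thrsp (2.79) (camera adjusted p = 1.54e-05; adjusted p = 0.636 with an estimated correlation). Of 19 lipid uptake and droplet genes 3 rose, Pparg (1.49), the droplet protein Cidec (2.60) and Cd36, with 4 up and 2 down adjusted over the list alone (camera adjusted p = 0.485).

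Bile acid transporters Slco1a4 (4.38), Abcc3 (2.41) and Abcc2 (0.63) rose, 3 of 12 (3 up and 2 down adjusted over the list alone, camera adjusted p = 0.149). Of 13 bile acid synthesis genes 3 rose and 3 fell, with 4 and 3 adjusted over the list alone (camera adjusted p = 0.754): Akr1d1 (1.60) was among the first, and Cyp39a1 (-2.0), Cyp7b1 and Cyp2c70 (-0.95) fell. Other large rises were Cyp3a59 (5.58), Cyp2c53-ps (4.71) and the glucuronosyltransferase Ugt1a9 (4.45). Large falls were Mup9 (-3.91), Mup1 (-3.20), Serpina12 (-2.75), the secreted Enho (-2.66), the anion carrier Slc22a7 (-2.39), Derl3 (-2.26), Ugt2b38 (-2.05), Avpr1a (-2.02) and Slc3a1 (-2.01). Of 14 stellate cell and fibrosis genes, Col1a1 (1.42) and Col3a1 (0.81) rose, 4 adjusted over the list alone (camera adjusted p = 0.097).

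With the 2 clock-shifted libraries left out, 538 genes passed, 447 of them shared, with 13 xenobiotic, 8 NRF2, 4 cholesterol and 3 fatty acid synthesis genes higher. Leaving out high-fat diet replicate 1 gave 543, high-fat diet replicate 11 gave 483, and replicates 3, 4 and 6 of the treated group gave 1353, 351 and 368. Of 63 named genes called, 36 passed in all 18 fits that left out 1 library. For others, brackets give the highest adjusted p in these fits and the number of the 18 that passed. The highest came without treated replicate 4 for Acacb (0.0703, 15), Cyp2c70 (0.121, 15), Elovl6 (0.0512, 17), Fdps (0.0662, 16), Mup1 (0.141, 14), Serpina12 (0.0572, 16), Thrsp (0.122, 14) and Ugt2b38 (0.177, 9), and without treated replicate 6 for Cyp39a1 (0.056, 17). It came without high-fat diet replicate 1 for Abcc2 (0.0956, 15) and without high-fat diet replicate 11 for Col3a1 (0.139, 3).

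**Figure D4:**
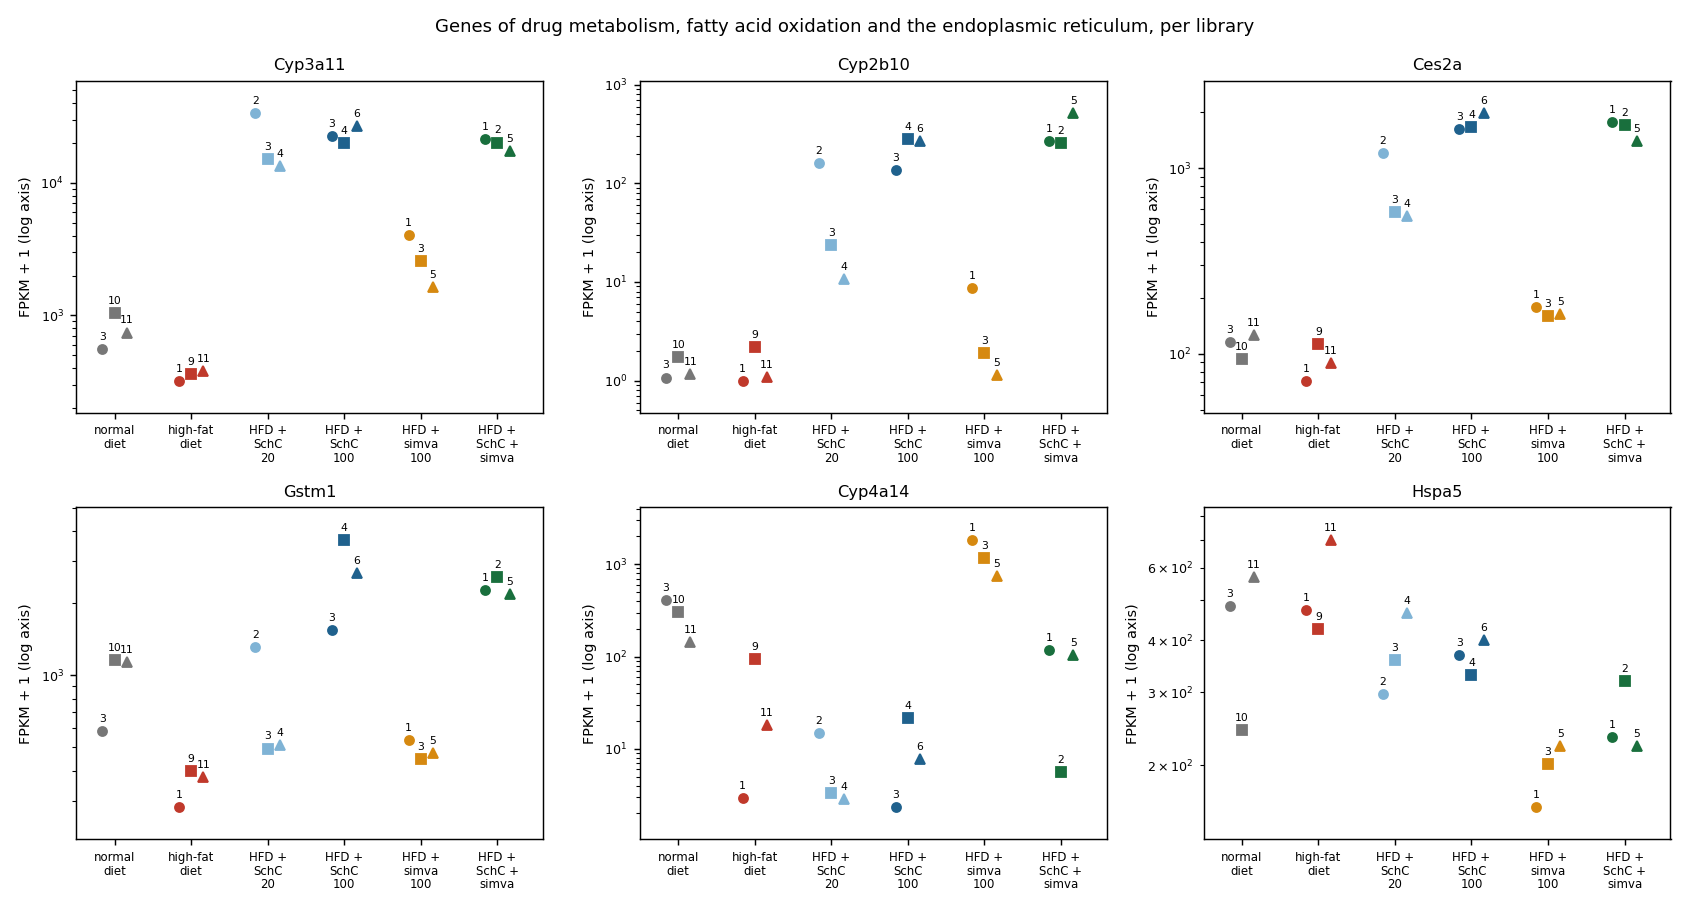
FPKM + 1 on a log axis of Cyp3a11, Cyp2b10, Ces2a, Gstm1, Cyp4a14 and Hspa5 in each library (points, numbered by replicate, SchC for schisandrin C, simva for simvastatin). Cyp3a11 stands at 320 to 377 FPKM on the high-fat diet and at 13500 to 33710 in the 9 libraries given schisandrin C, and Cyp4a14 at 746 to 1851 with simvastatin alone.

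Simvastatin alone was compared with the high-fat diet. Cyp4a14, a fatty acid hydroxylase, rose from 37.2 ± 48.5 to 1255 ± 558 FPKM (SD, n = 3, log2 fold change 6.10, SE 1.23), and the acyl-CoA thioesterase Acot1 from 10.8 ± 5.15 to 103 ± 43.1 (3.16, SE 0.45). Hspa5, the main chaperone of the endoplasmic reticulum, fell from 533 ± 147 to 193 ± 32.4 FPKM (-1.44, SE 0.28). In limma, 44 genes were higher and 29 lower.

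Of 29 PPARA targets 9 rose, none fell and 20 rose adjusted over the list alone, with Acot2 (3.18), Cyp4a31 (3.03) and Crat (1.52); the camera adjusted p was 1.96e-22 and the adjusted p = 0.227 with an estimated correlation. Simvastatin replicate 1 had the highest Cyp4a14 (1851 FPKM), and without the 2 clock-shifted libraries none of the 29 passed over all genes, 11 rose adjusted over the list alone, and their median log2 fold change was 0.60 against 0.62. Of 16 genes of the unfolded protein response 4 fell, Hspa5, Pdia4 (-0.82), Hyou1 (-1.22) and Xbp1 (-0.87), and 9 fell and 1 rose adjusted over the list alone (camera adjusted p = 6.53e-08; adjusted p = 0.227 with an estimated correlation). Without the same 2 libraries none of the 16 passed over all genes, and 8 fell adjusted over the list alone. Of 21 xenobiotic genes 3 rose, Cyp3a11 (2.87), Por (1.56) and Cyp3a25 (1.34), with 7 adjusted over the list alone and 1 without the 2 libraries (camera adjusted p = 8.62e-07; adjusted p = 0.298 with an estimated correlation). Of 19 lipid uptake and droplet genes 3 rose, the acyltransferase Mogat1 (1.97), Slc27a1 (1.31) and the lipase Pnpla2 (0.91), and adjusted over the list alone 6 rose and 1 fell (camera adjusted p = 8.19e-05; adjusted p = 0.298 with an estimated correlation).

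None of 25 cholesterol synthesis genes passed, over all genes or adjusted over the list alone, and their median log2 fold change was 0.52 (camera adjusted p = 1.93e-06; adjusted p = 0.364 with an estimated correlation). None of 20 fatty acid synthesis genes passed over all genes, and 7 rose adjusted over the list alone (camera adjusted p = 0.000179; adjusted p = 0.364 with an estimated correlation). Of 14 male-biased genes none passed, and adjusted over the list alone 1 rose and 6 fell (camera adjusted p = 5.77e-05; adjusted p = 0.346 with an estimated correlation). Of 9 female-biased genes Acot3 (4.83) rose, and 3 adjusted over the list alone (camera adjusted p = 1.05e-05; adjusted p = 0.298 with an estimated correlation). The bile acid exporter Abcc3 (1.25) rose, and 6 of 12 transport genes adjusted over the list alone (camera adjusted p = 0.028; adjusted p = 0.298 with an estimated correlation). Other large rises were Cyp3a59 (2.60), Slc16a5 (2.73), Acot4 (2.33) and the peroxisomal Ehhadh (2.34). Falls were Mup9 (-3.12), Serpina12 (-2.81), the ferritin receptor Scara5 (-2.36), Derl3 (-2.29), Capn8 (-1.81), the complement component C9 (-1.44), Gna14 (-1.43) and Sdr9c7 (-1.25).

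Of the 73 genes called, 3 were among the 6 that passed without the 2 clock-shifted libraries. Leaving out high-fat diet replicates 1, 9 and 11 gave 23, 210 and 21, simvastatin replicates 1 and 3 gave 14 each, schisandrin C 20 mg/kg replicate 3 gave 37 and combination replicate 1 gave 36. Of 30 named genes called, 8 passed in all 18 fits that left out 1 library: Acot1, Acot2, Crat, Cyp3a11, Cyp3a59, Cyp4a31, Gna14 and Mogat1. For others, brackets give the highest adjusted p in these fits and the number of the 18 that passed. The highest came without simvastatin replicate 1 for Cyp4a14 (0.175, 10), Hspa5 (0.175, 12), Mup9 (0.175, 9), C9 (0.175, 13), Cyp3a25 (0.175, 12), Pdia4 (0.19, 12), Hyou1 (0.231, 7), Xbp1 (0.23, 4) and Por (0.118, 11). The same library gave it for Abcc3 (0.14, 14), Pnpla2 (0.197, 5), Serpina12 (0.197, 10), Slc16a5 (0.117, 14), Capn8 (0.117, 14), Derl3 (0.0802, 15), Scara5 (0.0749, 15) and Sdr9c7 (0.0749, 17). It came without simvastatin replicate 3 for Acot3 (0.0547, 17), and without high-fat diet replicate 1 for Acot4 (0.129, 14), Ehhadh (0.0651, 16) and Slc27a1 (0.134, 12).

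Schisandrin C and simvastatin given together were compared with the high-fat diet alone. Cyp2b10 rose from 0.424 ± 0.650 to 345 ± 147 FPKM (SD, n = 3, log2 fold change 7.94, SE 0.81), Gstm3 to 1032 ± 191 (7.79, SE 0.95) and Cyp3a11 to 19740 ± 2035 (5.80, SE 0.35). Serpina1e, an alpha-1-antitrypsin gene, fell from 8531 ± 4127 to 473 ± 676 FPKM (log2 fold change -5.25, SE 1.17). In limma, 797 genes were higher and 507 lower. With quantile scaling these were 623 and 560.

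Of 21 xenobiotic genes 17 rose, none fell and 18 rose adjusted over the list alone, with Ces2a (4.18), Cyp2c55 (7.42) and Gadd45b (4.75) (camera adjusted p = 1.11e-20; adjusted p = 0.127 with an estimated correlation). Of 19 NRF2 targets 12 rose and 1 fell, 14 and 1 adjusted over the list alone, with Gstm1 (2.75) and the sulfiredoxin Srxn1 (1.42) (camera adjusted p = 1.98e-06; adjusted p = 0.406 with an estimated correlation). Gsta1, listed at 0 in the high-fat diet libraries, stood at 25.7, 37.0 and 26.5 FPKM. Of 25 cholesterol synthesis genes 7 rose, none fell and 12 rose adjusted over the list alone, with Tm7sf2 (1.33) and Acat2 (1.06) (camera adjusted p = 1.51e-06; adjusted p = 0.442 with an estimated correlation). Of 20 fatty acid synthesis genes 8 rose and none fell, also adjusted over the list alone, with Acss2 (1.36), Elovl6 (2.59), Acacb (1.97) and Pnpla3 (1.69) (camera adjusted p = 7.35e-05; adjusted p = 0.424 with an estimated correlation).

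Of 14 male-biased genes 1 rose and 10 fell, 2 and 10 adjusted over the list alone, among them Cyp2u1 (-2.08), Cyp7b1, Ugt2b38 (-2.67) and Nudt7 (-1.56) (camera adjusted p = 5.67e-05; adjusted p = 0.424 with an estimated correlation). Of 9 female-biased genes 7 rose and none fell, also adjusted over the list alone, among them Fmo2 (2.07), Abcd2 (2.11), Cyp3a44 (2.25) and Cyp3a16 (1.89) (camera adjusted p = 1.8e-05; adjusted p = 0.406 with an estimated correlation). The mean deviations of the male-biased list were -1.21, 0.15 and -0.84 in combination replicates 1, 2 and 5, and those of the female-biased list 1.99, 0.01 and 1.23. Without the 2 clock-shifted libraries 4 male-biased genes fell and 4 female-biased genes rose. Other falls were Serpina4-ps1 (-4.93), Mup1 (-4.67), Mup9 (-4.61), Mup12 (-3.43), Mup14 (-2.61), Serpina12 (-3.70), Slc22a7 (-2.70) and Derl3 (-2.65), and other rises Sult2a7 (5.25), Cyp3a59 (5.71), Ugt1a9 (5.04) and Slco1a4 (4.37).

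Of 16 unfolded protein response genes 1 rose and 6 fell, 2 and 8 adjusted over the list alone, with Sdf2l1 (-1.85), Pdia4 (-0.72) and Hspa5 (-1.03) lower and Trib3 (0.86) higher (camera adjusted p = 0.0148; adjusted p = 0.511 with an estimated correlation). Of 29 PPARA targets 4 rose and 1 fell, 5 and 1 adjusted over the list alone, with Crat (1.19), Acot3 (3.36), Vnn1 (1.64) and Acot4 (1.67) (camera adjusted p = 0.132). Of 15 pericentral genes Cyp2a5 (2.57) and Oat (1.32) rose and Lgr5 (-0.99) and Gulo (-0.69) fell, with the same counts adjusted over the list alone (camera adjusted p = 0.663). Of 12 bile acid transport genes 3 rose, Slco1a4, Abcc3 (2.36) and Abcc2 (0.83), and Slco1a1 (-1.60) fell, with 6 and 2 adjusted over the list alone (camera adjusted p = 0.0483; adjusted p = 0.406 with an estimated correlation).

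Leaving out the 2 clock-shifted libraries, 683 genes passed, 622 of them shared, with 14 xenobiotic, 9 NRF2, 3 cholesterol and 3 fatty acid synthesis genes higher. Leaving out high-fat diet replicate 1 gave 707, and combination replicates 1, 2 and 5 gave 665, 830 and 800. Of 77 named genes called, 45 passed in all 18 fits that left out 1 library. For others, brackets give the highest adjusted p in these fits and the number of the 18 that passed. The highest came without combination replicate 1 for Acot3 (0.0536, 17), Gulo (0.113, 12), Mup14 (0.184, 8), Pnpla3 (0.0784, 15), Sdf2l1 (0.0527, 17), Serpina1e (0.0532, 17), Serpina4-ps1 (0.0721, 16), Vnn1 (0.0616, 16) and Alas2 (0.0503, 17). It came without replicate 2 for Kdr (0.094, 16) and without replicate 5 for Pdia4 (0.0525, 16) and Slco1a1 (0.144, 14). Without high-fat diet replicate 1 it came for Acot4 (0.118, 16) and Cdh5 (0.0824, 15), and without high-fat diet replicate 11 for Acacb (0.0612, 16), Hspa5 (0.104, 14) and Trib3 (0.0963, 13).

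Between the 2 doses of schisandrin C, Gstm1, Ces2a, Ass1 and Col1a1 were among the genes that differed. Gstm1 stood at 2638 ± 1073 FPKM at 100 mg/kg and 771 ± 466 at 20 mg/kg (SD, n = 3, log2 fold change 1.84, SE 0.37), and Ces2a at 1757 ± 193 and 779 ± 370 (1.27, SE 0.25). Cyp3a11 stood at 23260 ± 3602 and 20810 ± 11210 FPKM. Ass1, a urea cycle enzyme, was lower at 100 mg/kg (83.1 ± 31.9 against 213 ± 16.8 FPKM, log2 fold change -1.41, SE 0.27), and Col1a1 higher (6.94 ± 2.60 against 1.45 ± 0.692, 1.69, SE 0.30). In limma, 918 genes were higher and 1403 lower at 100 mg/kg.

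Of 21 xenobiotic genes 7 were higher, also adjusted over the list alone, with Gadd45b (2.81) and Akr1b7 (1.80) (camera adjusted p = 0.0519). Of 19 NRF2 targets 6 were higher and 1 lower (Gclm, -0.51), also adjusted over the list alone, Gstm3 (4.15) among the first (camera adjusted p = 0.0519). Of 14 stellate cell and fibrosis genes 7 were higher, with 7 up and 1 down adjusted over the list alone, among them Col1a2 (1.16) and Sparc (0.52) (camera adjusted p = 0.0215; adjusted p = 0.995 with an estimated correlation). Of 20 fatty acid synthesis genes 3 were higher, and 6 adjusted over the list alone, Pnpla3 (1.66) among them (camera adjusted p = 0.00472; adjusted p = 0.995 with an estimated correlation). Of the title genes, Cyp7a1 (-1.05, adjusted p = 0.0685), Cyp7b1 (-1.43, adjusted p = 0.0544) and Cd36 (0.25, adjusted p = 0.745) did not pass. Without schisandrin C 20 mg/kg replicate 2, Cyp7a1 (adjusted p = 0.03) and Cyp7b1 (0.024) did.

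Across genes the difference between the doses followed GC content (rho 0.59), and with the GC trend of each library removed 872 genes passed, 681 of them (29.3% of the 2321) shared. The list counts between the doses given above come from values without this correction, so they may partly follow GC content. Without schisandrin C 100 mg/kg replicate 4, 1110 passed, and Pnpla3 did not (adjusted p = 0.0657). With the 2 clock-shifted libraries left out, 2484 passed, 2226 of them shared. Of 57 genes called here under the naming rule, 26 passed in all 18 fits that left out 1 library.

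Schisandrin C and simvastatin were compared at the same dose of 100 mg/kg. Gstm3 stood at 745, 2035 and 1583 FPKM with schisandrin C and 19.1, 5.67 and 6.72 with simvastatin (log2 fold change 7.05). Ces2a stood at 1757 ± 193 FPKM with schisandrin C and 167 ± 9.45 with simvastatin (SD, n = 3, log2 fold change 3.39, SE 0.25), and Cyp3a11 at 23260 ± 3602 and 2752 ± 1227 (3.17, SE 0.35). Cyp4a14 stood at 9.55 ± 9.83 and 1255 ± 558 FPKM (-7.32, SE 1.23) and Ehhadh at 67.4 ± 19.1 and 435 ± 311 (-2.45, SE 0.38). In limma, 297 genes were higher and 183 lower with schisandrin C, and with quantile scaling 257 and 209. Of 21 xenobiotic genes 13 were higher and 1 lower (15 and 2 adjusted over the list alone, camera adjusted p = 8.77e-14; adjusted p = 0.321 with an estimated correlation). Of 29 PPARA targets 12 were lower and none higher (20 lower adjusted over the list alone, camera adjusted p = 9.59e-15; adjusted p = 0.321 with an estimated correlation). Of 19 NRF2 targets 6 were higher and none lower (9 adjusted over the list alone, camera adjusted p = 5.6e-07; adjusted p = 0.321 with an estimated correlation). Hamp, which encodes the iron hormone hepcidin, was lower (481 ± 171 against 2770 ± 1109 FPKM, -2.52, SE 0.47). Leaving out schisandrin C replicates 3, 4 and 6 gave 722, 254 and 160 genes, and simvastatin replicates 1, 3 and 5 gave 227, 228 and 306. With the 2 clock-shifted libraries left out, 343 passed, 280 of them shared.

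The combination was compared with simvastatin alone. Cyp2c29 stood at 4707 ± 645 and 421 ± 52.2 FPKM (SD, n = 3, log2 fold change 3.48, SE 0.36), and Cyp2a5, a coumarin hydroxylase, at 1460 ± 355 and 283 ± 20.1 (2.34, SE 0.38). Ehhadh (-2.12) and Mogat1 (-1.73) were lower. In limma, 304 genes were higher and 158 lower (257 and 189 with quantile scaling), and without the 2 clock-shifted libraries 376 passed, 311 of them shared. Of 21 xenobiotic genes 15 were higher and none lower, with 17 and 1 adjusted over the list alone (camera adjusted p = 2.23e-17; adjusted p = 0.216 with an estimated correlation). Of 29 PPARA targets 7 were lower and none higher, with 18 lower adjusted over the list alone (camera adjusted p = 1.51e-12; adjusted p = 0.577 with an estimated correlation). Leaving out simvastatin replicates 3 and 5 gave 219 and 246 genes, and combination replicates 1, 2 and 5 gave 199, 290 and 268.

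Between the combination and schisandrin C at 100 mg/kg, limma called 0 genes, with 1075 at an unadjusted p under 0.05. With array weights 63 passed, without the 2 clock-shifted libraries 5, with the clock score as a covariate 3, and with no filter, a filter at 5 FPKM or these 2 groups alone 2 each. The 6 genes with the smallest p did not pass. Of these, the matrix genes Igfbp7 (45.6 ± 2.16 against 77.1 ± 3.17 FPKM, SD, n = 3, adjusted p = 0.067), Emilin1 (5.60 ± 0.664 against 9.28 ± 0.387, adjusted p = 0.067), Col4a1 (8.27 ± 0.456 against 16.6 ± 0.816, adjusted p = 0.118) and Sparc (15.1 ± 0.901 against 24.6 ± 2.03, adjusted p = 0.118) had log2 fold changes of -0.75, -0.64, -0.93 and -0.67. The others were Tle3 (-0.68, adjusted p = 0.118) and Snord47 (adjusted p = 0.118), a small nucleolar RNA listed at 0 in all 3 libraries of schisandrin C at 100 mg/kg. Snord47 was also at 0 in high-fat diet replicates 1 and 9, against 22470 FPKM in replicate 11 and 9354 to 16870 at 20 mg/kg. Leaving out high-fat diet replicate 1 gave 9 genes, high-fat diet replicate 9 and combination replicate 2 gave 4 each, high-fat diet replicate 11 gave 2, and schisandrin C 100 mg/kg replicate 3 and simvastatin replicates 1 and 5 gave 1 each. Without high-fat diet replicate 1, Igfbp7 (adjusted p = 0.0219), Emilin1 (0.0157), Col4a1 (0.00265) and Sparc (0.0219) passed, and the 18 fits that left out 1 library gave up to 0.513 for the last 3 and 0.402 for Igfbp7. Of 14 stellate cell and fibrosis genes none passed over all genes, and 4 were lower adjusted over the list alone (camera adjusted p = 5.48e-08; adjusted p = 0.221 with an estimated correlation).

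Departure from additivity of the combination was called in 0 genes by limma, with 1007 at an unadjusted p under 0.05. With array weights 79 genes departed, with no filter 1, with a filter at 5 FPKM 2 and without the 2 clock-shifted libraries 2. Of 29 PPARA targets none passed over all genes. Adjusted over the list alone, 10 were below the sum of the single drugs' log2 fold changes. The median departure was -0.68 (camera adjusted p = 3.04e-14, and 0.45 with an estimated correlation). The schisandrin C dose in the combination is in doubt, so a departure may also reflect that dose. Leaving out high-fat diet replicate 1, simvastatin replicate 1 and combination replicate 2 gave 1 gene each, schisandrin C 20 mg/kg replicate 2 gave 3 and simvastatin replicate 5 gave 6.

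Markers of other liver cells and the lists not given above were compared in the same way. With the combination Clec4f, a Kupffer cell lectin, fell from 70.0 ± 40.3 to 25.2 ± 4.11 FPKM (SD, n = 3, log2 fold change -1.31, SE 0.28), with 11 of 14 macrophage genes lower adjusted over the list alone (camera adjusted p = 3.89e-06; adjusted p = 0.424 with an estimated correlation). High-fat diet replicate 1 held 116 FPKM of Clec4f, and without the 2 clock-shifted libraries 1 gene of the list fell adjusted over the list alone. The macrophage list passed camera, with no gene called over all genes, for simvastatin (9 lower adjusted over the list alone, adjusted p = 1.1e-08; 0.298 with an estimated correlation), 20 mg/kg (none, adjusted p = 0.0128; 0.992) and 100 mg/kg (none, adjusted p = 0.00343; 0.848). Without the 2 clock-shifted libraries no macrophage gene was lower adjusted over the list alone in these 3 comparisons, and 1 was higher at each schisandrin C dose. Of 13 endothelial genes 4 fell with the combination, the growth factor receptor Kdr (-0.51) and the cadherin Cdh5 (-0.61) among them (6 adjusted over the list alone, camera adjusted p = 0.000113; adjusted p = 0.424 with an estimated correlation), and without the 2 clock-shifted libraries none passed over all genes and 5 fell adjusted over the list alone. With the diet none of the 13 passed (camera adjusted p = 0.00891; adjusted p = 0.533 with an estimated correlation).

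Of 18 interferon response genes 2 rose with the diet, Ifit1 (0.96) among them, and 5 adjusted over the list alone (camera adjusted p = 0.00455; adjusted p = 0.533 with an estimated correlation), and Ifit1 passed in 14 of the 18 fits that left out 1 library (highest adjusted p = 0.123, without normal diet replicate 10). Of 19 NRF2 targets 1 fell with the diet and 2 adjusted over the list alone (camera adjusted p = 0.011; adjusted p = 0.533 with an estimated correlation). Of 21 xenobiotic genes 4 rose with the diet, and adjusted over the list alone 4 rose and 3 fell (camera adjusted p = 0.429). Of 25 cholesterol synthesis genes 1 rose with the diet, none adjusted over the list alone (camera adjusted p = 0.151). With simvastatin, camera passed for 21 acute phase genes (adjusted p = 0.00896; 0.555 with an estimated correlation), 19 NRF2 targets (0.028; 0.555) and 15 pericentral genes (0.0163; 0.364), with no gene of these called over all genes and 3 pericentral genes lower adjusted over the list alone. On acute phase genes high-fat diet replicate 1 stood apart, with Hp at 6989 FPKM against 2250 and 2232 in replicates 9 and 11 and Orm1 at 1179 against 375 and 357. The median log2 fold change of the acute phase list was -0.46 with simvastatin, and 0.03 without the 2 clock-shifted libraries. Of 6 cell cycle and 7 lymphocyte and neutrophil genes none passed in any comparison with the high-fat diet or between the diets. Of the lists too small to test, none of 3 cholangiocyte genes and 1 adipocyte gene passed in these 5 comparisons, and no mitochondrially encoded or skeletal muscle gene was measured. Of 2 blood cell genes Alas2 (-1.19) fell with the combination. The only measured exocrine pancreas gene, Cela1, rose with the diet (1.54) and fell with 100 mg/kg (-1.52) and the combination (-1.46). These calls of Cela1 passed in 2, 3 and 6 of the 18 fits that left out 1 library. The highest adjusted p were 0.195 without normal diet replicate 10, 0.175 without schisandrin C 100 mg/kg replicate 4 and 0.122 without high-fat diet replicate 11, in that order. Of 4 AHR targets 1 rose with the diet and 1 with the combination.

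The genes called between the diets were compared with those called under each treatment. Of 390 genes higher and 406 lower with the diet, 84 were called in the opposite and 50 in the same direction with schisandrin C at 100 mg/kg (32.2 and 31.9 if the calls were independent). With the combination they were 115 and 54 (47.7 and 47.3), with simvastatin 15 and 2 (2.7 and 2.6), and with schisandrin C at 20 mg/kg 18 and 151 (64.4 and 63.5). Both comparisons share the 3 high-fat diet libraries, which alone makes the changes oppose each other. In 100 simulations with no treatment effect the opposite count reached 160 for 20 mg/kg, 216 for 100 mg/kg, 55 for simvastatin and 2 for the combination, and the same-direction count 11, 26, 40 and 0. The simulations treated the 4 treatments alike, so their maxima differ only by the draws. Against the highest over all 4 (216 opposite and 40 in the same direction), no opposite count was higher. The same-direction counts of 20 mg/kg, 100 mg/kg and the combination (151, 50 and 54) lay above that maximum of 40. The simulations held no treatment effect, so any treatment effect, also one unrelated to the diet, could lift the counts above it. Against independent calls the combination's 54 was near 47.3, while 50 and 151 lay above 31.9 and 63.5. The mean simulated opposite counts were 1.8, 3, 0.6 and 0, so the large maxima, those of the single drugs, come from few draws. Each draw took the deviations of whole libraries with replacement. A group could thus hold copies of 1 library, which shrinks its spread and can inflate the maxima. The simulations therefore cannot decide whether the opposite counts show a return towards the normal diet or the shared libraries. Across genes, r between the diet change and the treatment change was -0.07 for 20 mg/kg, -0.31 for 100 mg/kg, -0.48 for simvastatin and -0.36 for the combination. The simulations gave -0.58 to 0.28, -0.56 to 0.08, -0.60 to 0.12 and -0.51 to 0.13, so that none of the 4 lay outside its range. For 20 mg/kg r was -0.165, -0.202 and -0.204 without high-fat diet replicates 1, 9 and 11, -0.14 without normal diet replicate 10 and -0.019 without normal diet replicate 11. Across genes the diet change followed GC content at rho -0.233, and the change with 20 mg/kg at -0.396, in the same direction. The changes with 100 mg/kg (0.255), simvastatin (0.217) and the combination (0.071) followed it in the opposite direction. How far GC content accounts for the counts above was not tested.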

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

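Of the settings, the removal of the GC trend, the fit without the 2 clock-shifted libraries (high-fat diet replicate 1 and simvastatin replicate 1) and the clock covariate were chosen after seeing the data. Of 418 calls of named genes, median-of-ratios scaling lost 0, array weights 12, pseudocount 0.1 18, quantile scaling 27, robust eBayes 33, GC removal 51, the clock covariate 64, no filter 96, the fit without the 2 libraries 118 and the replicate block 324, and at 5 FPKM 0 of 359 were lost. None of these calls reversed. The median-of-ratios factors were 0.9976 to 1.0119, so that rescaling could change little, and its 0 lost calls say little about robustness. Leaving out 1 library lost 963 of 7524. Except where stated below, the cause was not tested. Counts of genes called are given by setting.

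With no filter, simvastatin gave 39, the combination against schisandrin C 100 mg/kg 2 and departure from additivity 1. With the filter at 5 FPKM the last pair gave 2 and 2. With array weights, the diet gave 1425, schisandrin C 100 mg/kg 1945, simvastatin 399, the combination 1998, the doses 3489, schisandrin C against simvastatin 1280, the combination against simvastatin 1203, the combination against schisandrin C 63 and departure from additivity 79, and Cd36 between the combination and schisandrin C turned to -0.148. With the replicate number as a block, which leaves 4 residual degrees of freedom in place of 12, the diet gave 9, 20 mg/kg 3, 100 mg/kg 12, simvastatin 0, the combination 512, the doses 1503, schisandrin C against simvastatin 15, the combination against simvastatin 38 and any group 1297. In that fit r between diet and treatment changes was -0.247 for 20 mg/kg and -0.426 for 100 mg/kg, Cd36 between schisandrin C and simvastatin was -0.152, and Cyp7b1 between the combination and schisandrin C 0.056. The numbers do not pair the samples: the median r of 13 pairs with the same number was -0.05 and that of 122 other pairs 0.002.

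With the GC trend removed, 20 mg/kg gave 1047, the doses 872 and r for 20 mg/kg -0.126. Without the 2 clock-shifted libraries, which leaves fewer samples, 20 mg/kg gave 828, 100 mg/kg 538, simvastatin 6, the combination 683, the combination against schisandrin C 5 and departure from additivity 2, with r of -0.165 for 20 mg/kg and -0.384 for 100 mg/kg. With the clock covariate the diet gave 397 and the combination against schisandrin C 3, r was 0.059 for 20 mg/kg (a reversal), -0.132 for 100 mg/kg, -0.39 for simvastatin and -0.237 for the combination, and Cyp7a1 between the combination and simvastatin was -0.017. With the 2 compared groups alone, which leaves fewer samples, the diet gave 53, 20 mg/kg 34, 100 mg/kg 163, simvastatin 1, the combination 552, the doses 1176, schisandrin C against simvastatin 175 and the combination against schisandrin C 2. Of 207 list tests, 0 passed with an estimated correlation against 64, 32 with fry (28 shared) and 79 with the block (54 shared).

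Leaving out 1 library gave 231 to 813 for the diet, 610 to 2013 for 20 mg/kg, 351 to 1353 for 100 mg/kg, 14 to 210 for simvastatin, 665 to 1630 for the combination and 1110 to 2571 for the doses. It gave 160 to 722 for schisandrin C against simvastatin, 199 to 581 for the combination against simvastatin, 0 to 9 against schisandrin C, 0 to 6 for departure from additivity and 4178 to 5479 for any group. The r ranged from -0.204 to -0.019, -0.44 to -0.269, -0.599 to -0.422 and -0.476 to -0.321 for 20 mg/kg, 100 mg/kg, simvastatin and the combination. Uncalled title genes turned between treatments. Cd36 ranged from -0.352 (without schisandrin C 100 mg/kg replicate 3) to 0.49 for the combination against schisandrin C, from -0.226 (without simvastatin replicate 5) to 0.677 for the combination against simvastatin, from -0.063 (without schisandrin C 100 mg/kg replicate 6) to 0.779 for the doses, and from -0.403 (without simvastatin replicate 5) to 0.649 for schisandrin C against simvastatin. Cyp7a1 for the combination against simvastatin ranged from -0.144 (without simvastatin replicate 3) to 0.318. Depth is unknown in these values, so what it limits was not tested.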

Other observations

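The tests of diet, time of day and sample origin for the clock genes, both tests of the dose comparison and both tests on near-identical genes were chosen only after the result was seen.

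Clock genes placed high-fat diet replicate 1 and simvastatin replicate 1 beside the normal diet libraries. Diet as the whole cause is argued against by the pattern itself and by no separate test, since 2 of 15 libraries on the same diet had a clock score nearer to the normal diet mean. An origin of high-fat diet replicate 1 from an animal on the normal diet is argued against by its median position of 0.617 between the normal diet (0) and the other high-fat diet libraries (1) over 799 genes called without it, against 0.652 and 1.009 for replicates 9 and 11 and 0.067 to 0.287 for the normal diet libraries, each over the genes called without it. Collection at another time of day may explain the clock genes and stays open: 5 of 8 values of 4 further output genes lay nearer to the normal diet, Lpin1 in neither library, and no label gives a time. It could also enter the other genes called between the diets, of which 247 of 796 stayed called with the clock score as a covariate. For these genes diet and clock cannot be told apart fully. An effect of diet on the clock in part of the animals is a biological candidate explanation that was not tested. High-fat diet replicates 9 and 11 carry the unexplained column suffixes and high-fat diet replicate 1 does not. Within that group, what the suffixes mark cannot be told apart from the clock difference. None of the simvastatin libraries carries a suffix, so the suffixes do not set simvastatin replicate 1 apart.

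Genes changed between the 2 schisandrin C doses followed GC content across genes. GC content bias as the whole cause is argued against by 29.3% of the calls that passed in the same direction with each library's GC trend removed, and transcript length bias by a rho of -0.065. A GC bias of the schisandrin C 20 mg/kg libraries may still be a part of the cause, since 872 genes passed with that correction against 2321 without it. The dose itself stays open as a biological explanation, because all 3 libraries that stand apart in GC belong to a single dose group.

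With the combination 10 of 14 male-biased genes were lower and 1 higher than on the high-fat diet, and 7 of 9 female-biased genes higher, and neither list passed with an estimated correlation (adjusted p = 0.424 and 0.406). Animals of mixed sex are argued against by 2 genes. Over all 18 libraries the Y chromosome gene Ddx3y stood at 16.18 to 30.25 FPKM, and Xist, a transcript of female cells, at 0.115 or less. GC content bias is argued against by a smaller absolute list median of 1.521 with the GC trend removed, and the 2 clock-shifted libraries by 1.516 without them. Reads shared between near-identical genes are argued against by a median of -1.842 over 6 male-biased and 2.088 over 4 female-biased members outside such families, 3 of these 4 rising past the threshold. The female-biased list shares Cyp2b9, Cyp2b13 and Cyp3a16 with the xenobiotic list and Acot3 with the PPARA list. For these genes a rise with those lists was not told apart from a sex-biased change. A candidate explanation is an effect of the treatment on sex-biased genes, a hypothesis found and tested on the same data, and of the 3 combination libraries replicate 2 lay nearest to the high-fat diet libraries (mean deviations of 0.15 and 0.01 for the male-biased and female-biased lists, against 0.20 to 0.87 and -1.29 to -0.20). Low male-biased or high female-biased values also occurred elsewhere. On the normal diet the male-biased list stood at -0.03, -0.70 and -0.36, but the female-biased list was low too (-0.60, -0.97 and -0.88). With simvastatin alone the female-biased list stood at 0.87, 0.85 and 0.67 and the male-biased list at -0.40, -0.18 and 0.07.

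For each comparison of 3 against 3 libraries the 10 splits are too few for a share under 0.05, and 1 split, the real one, gave as many genes, except 10 for the combination against schisandrin C. There the real count of 0 fixes this in advance. The real count and the highest of the other splits were 796 and 1 for the diet, 1755 and 0 for 20 mg/kg, 880 and 1 for 100 mg/kg, 73 and 0 for simvastatin, 1304 and 1 for the combination and 2321 and 9 for the doses. They were 480 and 0 for schisandrin C against simvastatin, 462 and 0 for the combination against simvastatin, and 0 and 0 against schisandrin C (limma, 1075 at an unadjusted p under 0.05). For any group, 1 of 100 splits, the real one, gave as many genes (real 5071, highest other 109), which excludes chance. The splits do not test the clock genes or GC content, which in part follow the groups. For departure from additivity 100 of 100 gave as many genes (limma, real 0, with 1007 at an unadjusted p under 0.05, highest other 263), which a real count of 0 fixes in advance. For the list tests 40 of 100 gave as many calls as the real 64 (highest other 91), so chance is not excluded for the list tests as a whole.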
